A study of Homo sapiens with 12 samples.

How the data were processed

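Polyadenylated RNA of RKO cells was sequenced in 12 libraries, 2 for each of 6 groups taken from the labels: wild type, the PRDM1 knockout derivatives KO2 and KO5, and derivatives overexpressing GFP, the alpha form or the beta form of PRDM1. The library kit was a stranded one per the labels. Per the submitters' processing notes TopHat, Bowtie2 and Cufflinks were used with genome build hg19; their versions and roles are not given, and neither the read counter nor whether it used the strand is stated.

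The authors deposited 1 file of counts per library, whole reads per gene symbol with no normalization. Each deposited count file held 26366 entries, of which 26364 were genes and 2 named no gene; those entries, reads without a gene (9.13% to 10.8% of gene counts plus these) and ambiguous reads (1.66% to 1.75%), were left out. The authors also deposited comparison tables of overexpression against knockout, made with DESeq2 per the file headers and names, in a version not stated. They hold log2 fold changes and their standard errors, by the authors, and whether these were shrunken is not stated. The deposited tables also hold p-values and adjusted p-values by the authors, a score by the authors (the Wald statistic), and 1 other column by the authors, the mean of normalized counts. Which libraries entered the deposited tables was tested by rebuilding that mean from each of 63 sets of groups. The deposited table named for both forms together was identical to the beta table and was not used.

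Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr at its default settings and the 6 groups, which left 12858 genes, and libraries were scaled by the trimmed mean of M values (TMM). A quasi-likelihood model (glmQLFit, robust) with a mean per group was fitted to all 12 libraries, so that the groups share an estimate of the spread, and 11 comparisons were tested with glmQLFTest and the Benjamini-Hochberg adjustment at 0.05. The knockout arm is the mean of KO2 and KO5 with equal weight, and the overexpression arm the mean of alpha and beta. Log2 CPM used a prior count of 2. Gene counts per library ranged from 19058967 to 55961821, so that a count of 0 allows up to 0.157 CPM in the shallowest library, taking 3 counts as the floor. Standard errors of fold changes are Wald errors from the fitted means and dispersions, with the quasi-likelihood dispersion held at 1 or more, so that they are not under the counting error. Intervals of count ratios are 95% exact binomial intervals and cover counting error only.

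Of the 22 gene lists tested, those reported covered intestinal stem cell genes, Wnt targets, intestinal differentiation markers, G1/S genes, G2/M genes, MYC and ribosome biogenesis genes, interferon-stimulated genes and antigen presentation genes. They further covered genes PRDM1 represses in lymphocytes, unfolded protein response genes, cholesterol synthesis genes, hypoxia and glycolysis genes, NF-kB targets, RAS/MAPK feedback genes, TGF-beta and BMP targets, epithelial genes and mesenchymal genes. The last were fibroblast markers, leukocyte markers, immediate early genes and replication-dependent histone genes. Lists were tested with camera of limma 3.58.1 on log2 CPM, with a preset correlation of 0.01 and beside it an estimated correlation, adjusted over the lists of a comparison. Members were counted at the adjustment over all genes and adjusted over the list alone. Reads of histone genes and of near-identical copies are uncertain, since how shared reads were counted is not stated.

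Overlaps of called genes were set beside the overlap of independent lists, n1 × n2 / N. Where the comparisons share controls they were also set beside 20 simulations of unchanged groups. Fisher's exact test was 2-sided for the 16 overlaps. The comparisons, lists, tests, gene-naming rule and alternatives were chosen before the data were examined, except those named as added later. The rule named PRDM1, MYC, LGR5, ASCL2 and EPHB3 whether or not they passed. For alpha or beta against GFP, knockout against wild type, and overexpression against knockout, it also named the 6 largest rises and 6 largest falls among genes that passed. These needed a mean of at least 5 CPM in the higher group, no overlap between replicates and a symbol that is not a LOC, LINC, MIR, SNOR or antisense name, and both derivatives or forms had to agree. Up to 4 rises and 4 falls were named in the other comparisons, and up to 3 members of each list. The text gives part of the genes the rule names, and 1 list, which passed in some comparisons, and some genes are not reported here.

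The alternatives were DESeq2 size factors, no low-count filter, the DESeq2 1.42.0 Wald test, only the compared groups in the fit, a replicate block, each library left out in turn and a test for changes beyond 1.5-fold (glmTreat). PRDM1 was also left out before scaling, each arm was taken as 1 group, and the authors' deposited tables were read at adjusted p under 0.05. A correction for transcript GC content, and the DESeq2 Wald test for overlaps, were added after the data were seen. GC content came from GENCODE release 29 and was matched for 94.3% of genes, with 11020 in the trend, whereas the order of genes along chromosomes came from a RefSeq table of a later build than hg19.

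The methods were tested on simulated data for alpha against GFP, with 50 changed genes per fold. edgeR, over 12700 genes, recovered 62% of genes changed 1.2-fold, 90% at 1.5-fold, 96% at 2-fold and 100% at 4-fold, and called 0.088% of unchanged genes. DESeq2, over 12858 genes, recovered 54%, 92%, 96% and 100% and called 0.0079% of unchanged genes. camera found a list of 20 genes shifted by 0.30 (adjusted p = 1.96e-44) and also called 1 of 21 unchanged lists.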

Results

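Polyadenylated RNA was sequenced from RKO cells, an established human colon carcinoma line, and from derivatives of it in which PRDM1 was removed or overexpressed. PRDM1 encodes a zinc finger protein known best as a transcriptional repressor of B cell genes during plasma cell differentiation. The series title places it in the growth of colon cancer organoids, and the comparisons ask which transcripts differ when the cells lose or gain it. The 12 libraries formed 6 groups of 2, namely wild type, the knockout derivatives KO2 and KO5, a derivative overexpressing GFP, and derivatives overexpressing the alpha or the beta form of PRDM1. Gene counts per library were 36503307 and 55961821 in wild type, 43970008 and 35604471 in KO2, and 30031390 and 28575682 in KO5. They were 25414550 and 27509340 with GFP, 23564364 and 20165608 with alpha, and 19058967 and 24170122 with beta. Of 26364 genes in the files, 12858 had enough counts to be tested. Fold changes are given as log2 values ± standard error with n = 2 libraries per group, and adjusted p-values are from edgeR's quasi-likelihood F-test with Benjamini-Hochberg adjustment.

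The labels do not say whether the libraries of a group came from separate cultures. The p-values therefore measure only the spread between these libraries, which was small, with a common biological coefficient of variation of 2.18%. In a principal component analysis the first component, with 50.9% of the variance, placed the alpha and beta libraries between 35.4 and 35.9 and all other libraries below -10.5. The second, with 18.9%, placed KO5 at 29.6 and 31.0 and KO2 at -22.2 and -21.7.

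PRDM1 itself was almost absent from wild-type cells. The wild-type libraries held 4 and 4 PRDM1 counts, the KO2 libraries 0 and 1, the KO5 libraries 1 and 1, and the GFP libraries 2 and 6. With alpha the counts were 11475 and 9681, or 487 and 480 CPM (counts scaled by the gene counts of the library), and with beta 22395 and 28423, or 1175 and 1176 CPM. Against GFP, PRDM1 was higher by a ratio of 3200.5 (95% interval 1624 to 7414) with alpha and of 7777 (95% interval 3947 to 18014) with beta. The beta libraries held more PRDM1 transcripts than the alpha libraries, by a ratio of 2.43 (95% interval 2.39 to 2.47). The ratio of wild type to both knockouts together was 3.99 (95% interval 0.956 to 23.3), so at this depth the loss of PRDM1 transcripts was not detectable, and the counts do not test the edited site. Intervals here and below cover counting error only. Counts per gene do not tell the alpha and beta transcripts apart.

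**Figure D1:**
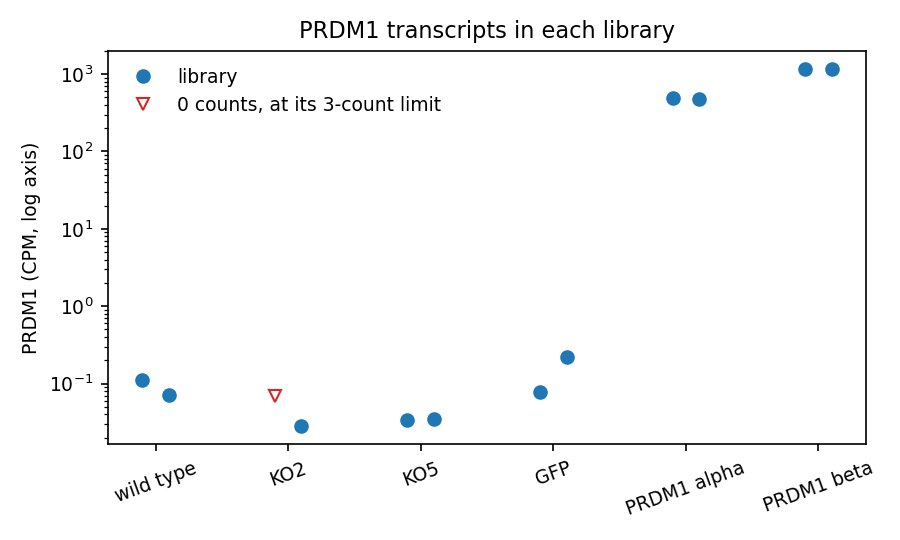
PRDM1 in CPM on a log axis, with 1 point per library and libraries grouped by derivative; the open triangle marks the library with 0 counts, drawn at its limit of 3 counts. The alpha libraries sit at 487 and 480 CPM and the beta libraries at 1175 and 1176, far above every library of the other groups.

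Of the genes always reported, the stem cell gene LGR5 had 0 counts in every library, which allows at most 0.157 CPM in the shallowest. ASCL2, a stem cell transcription factor, had 0 to 2 counts per library and EPHB3, an ephrin receptor, 0 to 4, too few to be tested. MYC was abundant, at 346 ± 2.13 CPM (mean ± SD, n = 2) in wild type and 332 ± 14.8 CPM with GFP.

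The alpha form was compared with GFP to find transcripts that follow from PRDM1 overexpression. Among genes of at least 5 CPM in the higher group, the largest rises included genes of proteases and of a protease inhibitor. The matrix metalloproteinase genes MMP3 and MMP1 rose by 8.99 ± 0.60 (adjusted p = 4.63e-36) and 6.76 ± 0.76 (adjusted p = 8.61e-23). The protease inhibitor gene SERPINB7 rose by 7.67 ± 0.67 and the carboxypeptidase gene CPA4 by 7.19 ± 0.18, from 1.26 ± 0.305 to 184 ± 5.33 CPM. ACSL5, a fatty acid CoA ligase, rose by 6.57 ± 0.78 and PADI1, a peptidylarginine deiminase, by 5.77 ± 0.60. FAM198B fell by 4.20 ± 0.18 (adjusted p = 1.01e-32), and TLR3, a receptor for viral RNA, fell by 2.95 ± 0.25. ADAMTSL1 fell by 2.81 ± 0.10, the phosphodiesterase gene PDE7B fell by 2.31 ± 0.06, and the interferon-induced GTPase gene GBP3 fell by 2.26 ± 0.18. SFTA1P, a pseudogene transcript, fell by 2.21 ± 0.07. In all, 2729 genes rose and 2095 fell, of which 221 and 139 changed at least 2-fold. The size of the leading rises rests on few control counts, since the GFP group held 7 counts of MMP3, 4 of MMP1, 5 of SERPINB7, 4 of ACSL5 and 6 of PADI1.

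Among the 22 gene lists, interferon and antigen presentation genes were lower with alpha. Of 24 tested interferon-stimulated genes 1 rose, 13 fell and 10 did not pass (adjusted p = 0.00580, and 0.145 with an estimated correlation), and IFIT1, an antiviral effector, fell by 4.56 ± 0.61 while USP18, a negative regulator of interferon signalling, fell by 0.95 ± 0.11. Of 16 antigen presentation genes 2 rose, 9 fell and 5 did not pass (adjusted p = 0.00237, and 0.145 with an estimated correlation). The peptidase gene ERAP2 fell by 1.74 ± 0.08, TAPBP of the peptide loading complex fell by 0.98 ± 0.06 and the MHC class I light chain gene B2M fell by 0.41 ± 0.03. Of 52 G2/M genes 5 rose, 25 fell and 22 did not pass (adjusted p = 2.54e-04, and 0.145 with an estimated correlation), with small falls such as that of NCAPD2, a condensin subunit, which fell by 0.26 ± 0.03, and of CKS2, which fell by 0.26 ± 0.04. Of 10 intestinal stem cell genes 1 rose, 5 fell and 4 did not pass (adjusted p = 0.0478, and 0.145 with an estimated correlation), and CDK6 fell by 0.38 ± 0.04 and ALCAM fell by 0.57 ± 0.07.

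Cholesterol synthesis, unfolded protein response, immediate early, TGF-beta and mesenchymal genes were higher with alpha. Of 21 cholesterol synthesis genes 13 rose, 2 fell and 6 did not pass (adjusted p = 0.00580, and 0.385 with an estimated correlation); HMGCS1 rose by 0.76 ± 0.04 and IDI1 by 0.60 ± 0.04, both enzymes of the mevalonate pathway. Of 20 unfolded protein response genes 12 rose, 2 fell and 6 did not pass (adjusted p = 0.00730, and 0.145 with an estimated correlation), and CRELD2 rose by 0.62 ± 0.07 while ASNS, asparagine synthetase, fell by 0.60 ± 0.04. Of 16 immediate early genes 11 rose, 1 fell and 4 did not pass (adjusted p = 0.00237, and 0.145 with an estimated correlation), and the transcription factor genes EGR1 and JUNB rose by 0.48 ± 0.05 and 0.73 ± 0.09. Of 13 TGF-beta and BMP targets 8 rose, 1 fell and 4 did not pass (adjusted p = 0.0478, and 0.145 with an estimated correlation); SKIL rose by 0.97 ± 0.07 and ID3 fell by 1.11 ± 0.05. Of 8 mesenchymal genes 3 rose, 0 fell and 5 did not pass (adjusted p = 0.0478, and 0.161 with an estimated correlation), and the receptor kinase gene AXL rose by 0.87 ± 0.03 and SNAI2, a repressor of epithelial genes, by 2.83 ± 0.26. The other 12 lists reported did not pass the list test, with adjusted p from 0.115 to 0.994. Wnt targets counted 4 rises and 3 falls among 11 tested members, intestinal differentiation markers 0 and 1 among 3 and G1/S genes 5 and 12 among 41. MYC and ribosome biogenesis genes gave 7 rises and 6 falls among 28 tested members, genes PRDM1 represses in lymphocytes 3 and 2 among 9 and hypoxia and glycolysis genes 3 and 5 among 19. NF-kB targets had 4 rises and 4 falls among 13 tested members, RAS/MAPK feedback genes 7 and 5 among 14 and epithelial genes 2 and 4 among 8. Fibroblast markers showed 2 rises and 1 fall among 4 tested members, leukocyte markers 2 and 0 among 2 and replication-dependent histone genes 4 and 0 among 12. Adjusted over the list alone, the counts of the lists reported were the same except for MYC and ribosome biogenesis genes (7 rises and 7 falls), genes PRDM1 represses in lymphocytes (4 rises and 2 falls), unfolded protein response genes (13 rises and 2 falls), hypoxia and glycolysis genes (3 rises and 6 falls), NF-kB targets (5 rises and 4 falls) and immediate early genes (12 rises and 1 fall). The median, the mean and the test differed in sign for intestinal differentiation markers, hypoxia and glycolysis genes and NF-kB targets.

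The leukocyte marker CD68 rose by 0.57 ± 0.07 and the fibroblast marker POSTN was higher by a ratio of 57.3 (interval 19.2 to 281, from 3 counts with GFP), whereas PTPRC, CD3E and CSF1R had 0 to 1 counts in any library. AXIN2, a feedback gene of Wnt signalling, fell by 1.00 ± 0.05 and the early response gene IER3 rose by 1.30 ± 0.07. MYC fell by 0.09 ± 0.03 (adjusted p = 0.0152), a call lost without GFP replicate 2 (-0.06), alpha replicate 1 (-0.09) or alpha replicate 2 (-0.10). A test for changes beyond 1.5-fold passed 360 genes.

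The beta form gave a response of the same kind. SERPINB7 rose by 6.78 ± 0.67, MMP3 by 6.07 ± 0.61 (adjusted p = 1.62e-21) and CPA4 by 6.05 ± 0.18, to 83.8 ± 3.22 CPM. The hexokinase-like gene HKDC1 rose by 5.47 ± 0.41, the secretogranin gene SCG2 by 4.94 ± 0.25 and the transglutaminase gene TGM2 by 3.68 ± 0.08. TLR3 fell by 6.05 ± 0.70 (adjusted p = 6.94e-21), to 5 counts in both libraries together. GBP3 fell by 5.19 ± 0.45, ADAMTSL1 fell by 4.73 ± 0.17, PDE7B fell by 3.97 ± 0.09 and FAM198B fell by 3.80 ± 0.16. JAG1, a Notch ligand, fell by 3.46 ± 0.05 (adjusted p = 3.66e-48). In all, 2945 genes rose and 2316 fell, of which 182 and 207 changed at least 2-fold.

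Of 24 interferon-stimulated genes 0 rose, 11 fell and 13 did not pass with beta (adjusted p = 0.00120, and 0.113 with an estimated correlation), and USP18 fell by 1.45 ± 0.12 and IFIT1 fell by 4.33 ± 0.57. Of 16 antigen presentation genes 2 rose, 9 fell and 5 did not pass (adjusted p = 0.00215, and 0.148 with an estimated correlation); the immunoproteasome gene PSMB9 fell by 3.02 ± 0.29, ERAP2 fell by 2.97 ± 0.10 and TAPBP fell by 1.53 ± 0.06. Of 52 G2/M genes 4 rose, 26 fell and 22 did not pass (adjusted p = 1.03e-04, and 0.148 with an estimated correlation), and NCAPD2 fell by 0.40 ± 0.03 and HMGB2 fell by 0.30 ± 0.03. Of 16 immediate early genes 9 rose, 2 fell and 5 did not pass (adjusted p = 0.0160, and 0.148 with an estimated correlation), with rises of 0.65 ± 0.06 in JUN and 0.74 ± 0.09 in JUNB. Of 8 mesenchymal genes 6 rose, 1 fell and 1 did not pass (adjusted p = 0.0164, and 0.148 with an estimated correlation), and AXL rose by 0.81 ± 0.03. The other 16 lists reported did not pass the list test, with adjusted p from 0.0728 to 0.998. Intestinal stem cell genes counted 1 rise and 5 falls among 10 tested members, Wnt targets 5 and 3 among 11 and intestinal differentiation markers 1 and 1 among 3. G1/S genes gave 5 rises and 10 falls among 41 tested members, MYC and ribosome biogenesis genes 5 and 8 among 28 and genes PRDM1 represses in lymphocytes 2 and 2 among 9. Unfolded protein response genes had 8 rises and 2 falls among 20 tested members, cholesterol synthesis genes 11 and 3 among 21 and hypoxia and glycolysis genes 4 and 5 among 19. NF-kB targets showed 3 rises and 5 falls among 13 tested members, RAS/MAPK feedback genes 6 and 5 among 14 and TGF-beta and BMP targets 8 and 3 among 13. Epithelial genes held 2 rises and 3 falls among 8 tested members, fibroblast markers 1 and 0 among 4 and leukocyte markers 1 and 0 among 2. Replication-dependent histone genes counted 5 rises and 0 falls among 12 tested members. Adjusted over the list alone, the counts of the lists reported were the same except for G2/M genes (4 rises and 27 falls), interferon-stimulated genes (0 rises and 12 falls), antigen presentation genes (3 rises and 10 falls), genes PRDM1 represses in lymphocytes (3 rises and 2 falls), unfolded protein response genes (8 rises and 3 falls), epithelial genes (3 rises and 4 falls), fibroblast markers (2 rises and 0 falls) and immediate early genes (10 rises and 2 falls). The median, the mean and the test differed in sign for hypoxia and glycolysis genes, TGF-beta and BMP targets and epithelial genes. After removal of the GC trend described below, lists that newly passed were cholesterol synthesis genes (9 higher and 3 lower, adjusted p = 0.0389) and TGF-beta and BMP targets (8 higher and 3 lower, adjusted p = 0.0389); neither passed with an estimated correlation (0.548 and 0.140).

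With beta, CD68 rose by 0.43 ± 0.08, AXIN2 fell by 0.95 ± 0.05 and IER3 rose by 1.49 ± 0.07. MYC stood at 0.03 ± 0.03 (adjusted p = 0.531), with -0.0176 when GFP replicate 1 was left out. A test for changes beyond 1.5-fold passed 353 genes.

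Both forms moved largely the same genes. Of the genes called, 2171 rose with both forms, where independent lists would share 625, and 1598 fell with both, where 377 would be shared. Only 10 rose with alpha and fell with beta and 1 did the opposite. The fold changes correlated across the 12858 genes (Pearson r = 0.87, Spearman 0.79), which are not independent replicates. Both comparisons share the GFP libraries. In 20 simulations of unchanged groups against shared controls the mean r was 0.45, and at most 1 gene was called in the same direction in both. The covariance was 0.261 against a simulated 0.0127. Part of the excess over independent lists may come from the shared controls, of which there are only 2 libraries. The simulations held only the spread between replicates, without a shift of whole libraries. GFP libraries differed from wild type along transcript GC content (Spearman -0.74), as described below. A shift in the GFP libraries would move both forms alike, so the simulations cannot tell its part in the overlap. After removal of the GC trend 4202 of the 4824 calls with alpha and 4805 of the 5261 with beta stayed called in the same direction. The overlap was not recounted for those. This r is 1 of 4 such relations computed.

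The forms were also compared directly. Relative to beta, alpha libraries held more MMP3 (2.92 ± 0.10, adjusted p = 2.97e-28), MMP1 (2.05 ± 0.19), JAG1 (1.97 ± 0.05) and RAB27B, a GTPase of vesicle secretion (2.05 ± 0.15). They held less SCG2 (-1.56 ± 0.11), less of the receptor gene GPRC5A (-1.41 ± 0.04, adjusted p = 5.60e-30), less ID2 (-0.94 ± 0.09) and less of the cell cycle inhibitor gene CDKN2B (-0.82 ± 0.10). In all, 443 genes were higher with alpha and 359 higher with beta, with 58 and 17 at least 2-fold. Of the 195 genes that rose with both forms and at least 2-fold with either, 94 differed between the forms, 68 larger with alpha and 26 with beta. Over all 2171 shared rises 260 differed, 135 larger with alpha and 125 with beta, since the smaller rises leaned the other way (67 and 99). Of the 159 genes that fell with both forms and at least 2-fold with either, 59 differed, 2 with the larger fall with alpha and 57 with beta. Over all 1598 shared falls 130 differed, 29 and 101. Of 20 unfolded protein response genes 5 were higher with alpha, 0 lower and 15 did not pass (adjusted p = 0.00423, and 0.358 with an estimated correlation), and adjusted over the list alone 6 were higher and 0 lower. The total of 802 genes fell to between 395 and 495 without any of the 4 libraries in turn (487 and 443 without alpha replicates 1 and 2, 495 and 395 without beta replicates 1 and 2), to 424 with the DESeq2 Wald test and to 59 for changes beyond 1.5-fold.

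**Figure D2:**
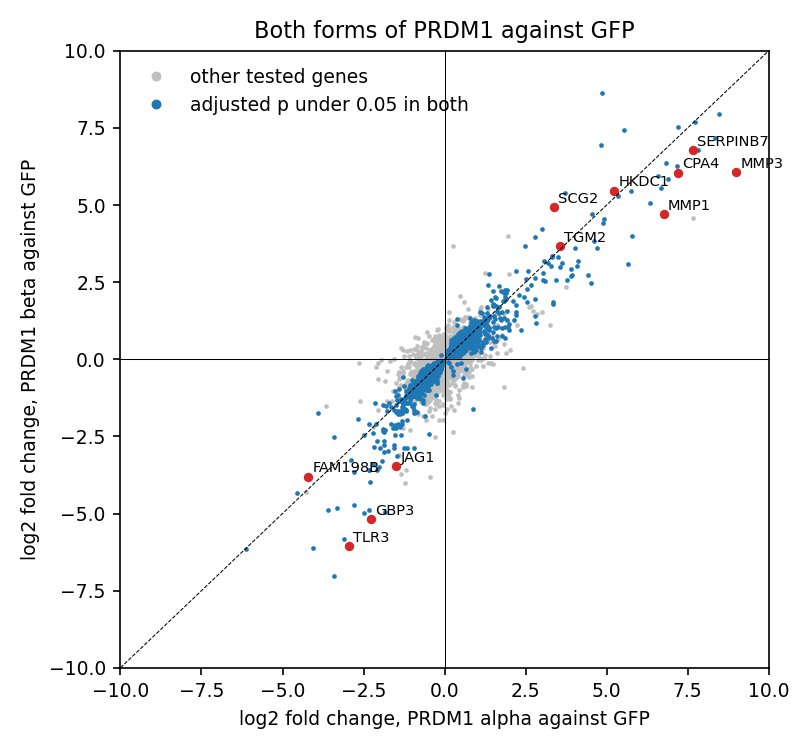
Fitted log2 fold change of each tested gene except PRDM1 with alpha (horizontal axis) and with beta (vertical axis) against GFP; blue points have adjusted p under 0.05 in both, and named genes are red. MMP3 lies at 8.99 with alpha and 6.07 with beta, and TLR3 at -2.95 and -6.05.

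The knockout derivatives were compared with wild-type cells, giving KO2 and KO5 equal weight. Among genes of at least 5 CPM in the higher group that agreed in both derivatives, the largest changes were falls, and zinc finger genes led them. ZFP82 fell by 5.85 ± 0.44 (adjusted p = 2.13e-27), ZNF569 fell by 4.66 ± 0.09 (adjusted p = 1.40e-43), ZFP28 fell by 3.69 ± 0.10 and ZNF471 fell by 3.22 ± 0.17, all genes of KRAB zinc finger proteins. ZNF569 went from 55.2 ± 1.04 CPM in wild type to 2.06 ± 0.241 in KO2 and 2.32 ± 0.0516 in KO5. SYTL3, a synaptotagmin-like gene, fell by 4.31 ± 0.22 and PCLO, a presynaptic scaffold gene, fell by 2.99 ± 0.13. The rises were smaller, the largest within the same limits being those of NAV3 (1.38 ± 0.05) and of IGF2BP3 (1.08 ± 0.03 in KO2 and 1.32 ± 0.03 in KO5, adjusted p = 5.14e-36 for both together), an RNA-binding protein of fetal tissues. The ribosomal RNA processing gene RRP15 rose by 0.72 ± 0.03, the chromatin gene HMGA2 by 0.72 ± 0.03 and the cyclin gene CCND1 by 0.65 ± 0.03. In all, 2223 genes rose and 2446 fell, of which 18 and 133 changed at least 2-fold. These fold changes fell with transcript GC content (Spearman -0.49). After removal of that trend, described below, 2824 of the 4669 calls stayed called in the same direction.

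Among the lists reported, MYC and ribosome biogenesis genes were higher in the knockouts and cholesterol synthesis genes lower. Taken singly, and before removal of the GC trend, the first list passed only in KO2 and the second only in KO5. Of 28 MYC and ribosome biogenesis genes 19 rose, 2 fell and 7 did not pass (adjusted p = 2.08e-05, and 0.0296 with an estimated correlation), with rises of 0.23 ± 0.03 in UTP20 and 0.19 ± 0.03 in WDR43. MYC rose by 0.19 ± 0.03 (adjusted p = 8.24e-08). Of 21 cholesterol synthesis genes 0 rose, 13 fell and 8 did not pass (adjusted p = 6.00e-05, and 0.432 with an estimated correlation). INSIG1 fell by 0.61 ± 0.04, the mean of an uneven fall (-0.15 ± 0.04 in KO2 and -1.06 ± 0.05 in KO5). DHCR7 fell in KO5 (-0.48 ± 0.04) and did not pass in KO2 (adjusted p = 0.983). The other 19 lists reported did not pass the list test, with adjusted p from 0.0599 to 0.906. Intestinal stem cell genes counted 5 rises and 2 falls among 10 tested members, Wnt targets 2 and 2 among 11 and intestinal differentiation markers 0 and 0 among 3. G1/S genes gave 5 rises and 10 falls among 41 tested members, G2/M genes 19 and 4 among 52 and interferon-stimulated genes 5 and 10 among 24. Antigen presentation genes had 2 rises and 6 falls among 16 tested members, genes PRDM1 represses in lymphocytes 1 and 3 among 9 and unfolded protein response genes 2 and 10 among 20. Hypoxia and glycolysis genes showed 4 rises and 5 falls among 19 tested members, NF-kB targets 3 and 6 among 13 and RAS/MAPK feedback genes 3 and 5 among 14. TGF-beta and BMP targets held 3 rises and 3 falls among 13 tested members, epithelial genes 3 and 1 among 8 and mesenchymal genes 2 and 1 among 8. Fibroblast markers counted 1 rise and 1 fall among 4 tested members, leukocyte markers 0 and 1 among 2 and immediate early genes 4 and 4 among 16. Replication-dependent histone genes gave 5 rises and 0 falls among 12 tested members. Adjusted over the list alone, the counts of the lists reported were the same except for Wnt targets (2 rises and 3 falls), G2/M genes (19 rises and 5 falls), interferon-stimulated genes (6 rises and 11 falls), antigen presentation genes (2 rises and 7 falls), unfolded protein response genes (3 rises and 10 falls), cholesterol synthesis genes (1 rise and 14 falls), hypoxia and glycolysis genes (4 rises and 6 falls) and RAS/MAPK feedback genes (4 rises and 5 falls). The median, the mean and the test differed in sign for Wnt targets, G1/S genes, hypoxia and glycolysis genes, TGF-beta and BMP targets, epithelial genes and mesenchymal genes. After removal of the GC trend described below, lists that newly passed were unfolded protein response genes (1 higher and 6 lower, adjusted p = 0.0382) and replication-dependent histone genes (4 higher and 0 lower, adjusted p = 0.0313); neither passed with an estimated correlation (0.279 for both).

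Of the mesenchymal genes, SNAI2 fell by 2.66 ± 0.41, from 75 counts in wild type to 10 in KO2 and 7 in KO5. The marker CD68 fell by 0.59 ± 0.06. The interferon-stimulated gene IFI35 fell by 0.61 ± 0.13, IRF7 fell in KO2 (-1.24 ± 0.20) and did not pass in KO5 (-0.18 ± 0.17, adjusted p = 0.379), and HERPUD1, of the unfolded protein response, fell by 0.29 ± 0.04. CDC20, an activator of the anaphase-promoting complex, rose by 0.28 ± 0.03. The topoisomerase gene TOP2A fell in KO5 (-0.37 ± 0.03) and did not pass in KO2 (0.07 ± 0.03, adjusted p = 0.0832). PRDM1 stood at -1.82 ± 1.02 (adjusted p = 0.0735), a fitted value that rests on 8 and 3 counts, and passed without KO2 replicate 2, at -2.84. The total fell from 4669 to 2610 without wild-type replicate 2, the deepest library, and to 126 for changes beyond 1.5-fold. With the 4 knockout libraries as 1 group, so that the spread also holds the difference between the derivatives, 337 genes passed, and HMGA2, CCND1, UTP20, WDR43, INSIG1, DHCR7, TOP2A, IRF7 and HERPUD1 did not. That fit still counts the 4 libraries as separate replicates and pools their spread with that of the other groups. The 337 may therefore still be too many.

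Taken singly, the derivatives shared the falls of ZFP82, ZNF569 and SYTL3 and differed in much else. In KO2, ZFP82 fell by 5.50 ± 0.49, ZNF569 fell by 4.75 ± 0.12, SYTL3 fell by 3.99 ± 0.25 and RAB34, a GTPase gene, fell by 6.37 ± 0.55. TCEB3, an elongin subunit, rose there by 1.89 ± 0.05, FAM198B by 1.81 ± 0.05, the laminin gene LAMB3 by 1.27 ± 0.11 and HMGA2 by 1.25 ± 0.03. In KO5, ZFP82 fell by 6.20 ± 0.73, SYTL3 fell by 4.63 ± 0.35 and ZNF569 fell by 4.57 ± 0.13, while FAM198B fell by 5.28 ± 0.23 (adjusted p = 4.98e-36), opposite to KO2. RAB34 rose in KO5 by 1.64 ± 0.08, also opposite to KO2. MFNG, a glycosyltransferase gene of the Notch pathway, rose by 3.24 ± 0.06, the collagen gene COL16A1 by 2.77 ± 0.20 and the pseudogene ANKRD20A12P by 2.12 ± 0.15. The last is uncertain, because reads can be shared with its near-identical copies. KO2 had 1939 rises and 1918 falls (31 and 199 at least 2-fold), and KO5 had 3244 and 3334 (123 and 198). After removal of the GC trend, 3691 of the 3857 calls in KO2 and 3915 of the 6578 in KO5 stayed called in the same direction. In KO2 the total of 3857 was 2563 without wild-type replicate 2, 2360 with the DESeq2 Wald test and 176 beyond 1.5-fold, and in KO5 280 genes passed beyond 1.5-fold.

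In KO2, 28 MYC and ribosome biogenesis genes gave 17 rises and 1 fall (adjusted p = 9.12e-08, and 0.0153 with an estimated correlation). Of 24 interferon-stimulated genes 0 rose, 10 fell and 14 did not pass there (adjusted p = 1.40e-04, and 0.0350 with an estimated correlation), and of 16 antigen presentation genes 0 rose, 8 fell and 8 did not pass (adjusted p = 0.0113, and 0.234 with an estimated correlation). Of 52 G2/M genes 21 rose, 3 fell and 28 did not pass (adjusted p = 1.43e-05, and 0.198 with an estimated correlation). Of 41 G1/S genes 13 rose, 2 fell and 26 did not pass (adjusted p = 0.0279, and 0.461 with an estimated correlation), and of 10 intestinal stem cell genes 5 rose, 0 fell and 5 did not pass (adjusted p = 0.0415, and 0.211 with an estimated correlation). In KO5, among the lists reported, of 21 cholesterol synthesis genes 1 rose, 12 fell and 8 did not pass (adjusted p = 0.00136, and 0.501 with an estimated correlation). Adjusted over the list alone, the rises and falls in KO2 were 19 and 1 for MYC and ribosome biogenesis genes, 0 and 12 for interferon-stimulated genes and 0 and 10 for antigen presentation genes. They were 25 and 3 for G2/M genes and 14 and 2 for G1/S genes, and the same as above for stem cell genes and for cholesterol synthesis genes in KO5. After removal of the GC trend the stem cell and G1/S calls in KO2 ended, at adjusted p = 0.0538 and 0.0580. Cholesterol synthesis genes did not pass the list test in KO2, also not after that removal (1 higher and 8 lower, adjusted p = 0.0572). In KO5, where that trend was strong (Spearman -0.55), 8 further lists passed after its removal: G1/S genes (1 higher and 22 lower, adjusted p = 2.26e-04), G2/M genes (7 higher and 25 lower, adjusted p = 0.0171), MYC and ribosome biogenesis genes (16 higher and 3 lower, adjusted p = 0.00160), unfolded protein response genes (2 higher and 8 lower, adjusted p = 0.0496), epithelial genes (6 higher and 0 lower, adjusted p = 0.00500), fibroblast markers (3 higher and 0 lower, adjusted p = 0.0496), immediate early genes (8 higher and 1 lower, adjusted p = 0.0496) and replication-dependent histone genes (5 higher and 0 lower, adjusted p = 0.0438). None of these passed with an estimated correlation (0.105 to 0.242).

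**Figure D3:**
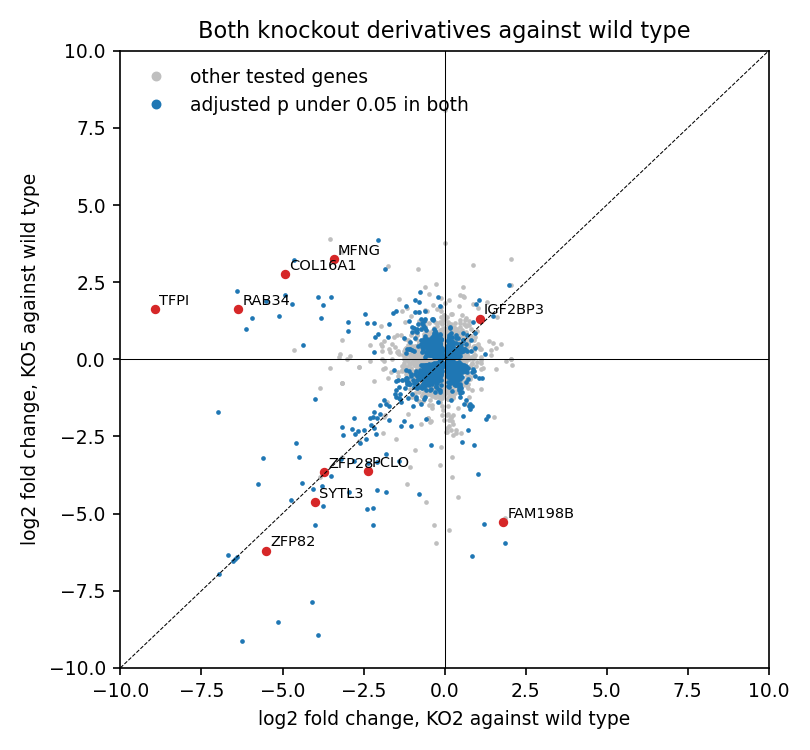
Fitted log2 fold change of each tested gene except PRDM1 in KO2 (horizontal axis) and KO5 (vertical axis) against wild type; blue points have adjusted p under 0.05 in both, and named genes are red. ZFP82 lies at -5.50 and -6.20, whereas FAM198B lies at 1.81 in KO2 and -5.28 in KO5.

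The overlap of the derivatives was modest. Of the genes called, 603 rose in both, against 489 for independent lists, and 689 fell in both, against 497. A further 524 rose in KO2 and fell in KO5, against 503 for independent lists, and 533 did the reverse, against 484. The fold changes correlated across genes with r = 0.26 (Spearman 0.08), where simulated unchanged groups against the shared wild-type libraries gave 0.43. The covariance was 0.0587 against a simulated 0.00776, and at most 1 gene was called in the same direction in both simulated comparisons. These simulations, too, held no shift of whole libraries. Part of the excess over independent lists may come from the shared controls. Fold changes followed GC content in KO5 (Spearman -0.55) and hardly in KO2 (-0.08). The overlaps were not recounted after removal of that trend. At least 2-fold changes were shared by 72 genes that fell in both derivatives and 4 that rose, HIST2H2BF, EDN1, PTCHD4 and IGF2BP3, named after their values were seen. Of these rises only IGF2BP3 was abundant in wild type, at 153 CPM. HIST2H2BF was at 0.0937 CPM there, EDN1 at 0.0625 and PTCHD4 at 0.390. Some of the falls also rest on few counts, such as that of HCN2, at 0.352 CPM in wild type and 0 counts in KO2 and KO5. Of the 72, 21 were zinc finger genes with ZNF or ZFP symbols, of which 455 were tested and 2.55 would be shared by chance (2-sided Fisher's exact test, p = 3.09e-14). The family was picked after the falls were seen, and the test treats genes as independent.

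A direct comparison of KO5 with KO2 passed 3453 genes higher in KO5 and 3609 lower, of which 264 and 177 differed at least 2-fold. These differences also followed GC content (Spearman -0.44). After removal of that trend 5161 of the 7062 calls stayed called in the same direction. TFPI, an inhibitor of blood coagulation, had 354 counts in KO5 and 0 in KO2, at least 160.2-fold higher if KO2 is put at a floor of 3 counts over the group, and the exact interval starts lower, at 129.6. COL16A1 had 357 counts against 2, a ratio of 242 (interval 66.6 to 2009), and the proteoglycan gene CSPG4 had 3 against 648, a ratio of 0.00629 (interval 0.00129 to 0.0185). RAB34 was higher in KO5 by 8.01 ± 0.55 and MFNG by 6.66 ± 0.17. FAM198B was lower, at -7.09 ± 0.23, GFPT2, an enzyme of the hexosamine pathway, at -6.54 ± 0.73 and the focal adhesion gene TNS4 at -4.75 ± 0.07. Of 24 interferon-stimulated genes 13 were higher in KO5 and 2 lower (adjusted p = 0.00879, and 0.112 with an estimated correlation). Of 52 G2/M genes 32 were lower and 10 higher (adjusted p = 0.0119, and 0.320 with an estimated correlation), of 41 G1/S genes 24 and 4 (adjusted p = 0.00879, and 0.320 with an estimated correlation), and of 13 NF-kB targets 8 and 2 (adjusted p = 0.0395, and 0.320 with an estimated correlation). Adjusted over the list alone, the counts of these 4 lists stayed as given. The NF-kB call ended after removal of the GC trend, at adjusted p = 0.0954, and lists that newly passed were antigen presentation genes (10 higher and 1 lower, adjusted p = 0.00489), cholesterol synthesis genes (4 higher and 10 lower, adjusted p = 0.0316), epithelial genes (7 higher and 0 lower, adjusted p = 0.00489) and fibroblast markers (3 higher and 0 lower, adjusted p = 0.0258), none with an estimated correlation (0.0682 to 0.443). A test for differences beyond 1.5-fold passed 441 genes.

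Overexpression was set against knockout to see which transcripts lie farthest apart between cells with much PRDM1 and cells without. ARL14EPL was 7.91 ± 0.81 higher with overexpression, SERPINB7 7.74 ± 0.58, CPA4 6.99 ± 0.13, ZFP82 6.62 ± 0.44 (adjusted p = 3.82e-33), MMP3 6.34 ± 0.28 and HKDC1 6.24 ± 0.36. TLR3 was lower, at -4.74 ± 0.37, ADAMTSL1 at -4.08 ± 0.10, GBP3 at -3.51 ± 0.24, PDE7B at -3.42 ± 0.05, JAG1 at -3.04 ± 0.03 (adjusted p = 2.24e-54) and SFTA1P at -3.04 ± 0.06. The sizes rest on few knockout counts for ARL14EPL (4 in KO2 and 1 in KO5), SERPINB7 (2 and 9) and ZFP82 (9 and 4). MYC was lower, at -0.29 ± 0.02 (adjusted p = 7.70e-16). In all, 3989 genes were higher with overexpression and 3568 lower, of which 325 and 198 differed at least 2-fold. The arms have different controls, so this comparison also holds the difference between GFP and wild-type libraries described below.

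Of 21 cholesterol synthesis genes 18 were higher with overexpression and 2 lower (adjusted p = 1.70e-04, and 0.178 with an estimated correlation), HMGCS1 by 0.93 ± 0.03 and IDI1 by 0.79 ± 0.03. Of 20 unfolded protein response genes 15 were higher and 0 lower (adjusted p = 4.47e-04, and 0.142 with an estimated correlation), with DNAJC3, a co-chaperone, at 0.42 ± 0.03. Of 16 immediate early genes 9 were higher and 2 lower (adjusted p = 0.0438, and 0.177 with an estimated correlation), with EGR1 at 0.67 ± 0.03. Of 28 MYC and ribosome biogenesis genes 21 were lower and 2 higher (adjusted p = 3.83e-04, and 0.101 with an estimated correlation). Of 52 G2/M genes 34 were lower and 4 higher (adjusted p = 1.12e-04, and 0.177 with an estimated correlation), and of 16 antigen presentation genes 11 and 4 (adjusted p = 0.00596, and 0.177 with an estimated correlation), with ERAP2 at -2.46 ± 0.06. The other 15 lists reported did not pass the list test, with adjusted p from 0.0832 to 0.938. Intestinal stem cell genes counted 1 rise and 5 falls among 10 tested members, Wnt targets 4 and 5 among 11 and intestinal differentiation markers 1 and 1 among 3. G1/S genes gave 15 rises and 11 falls among 41 tested members, interferon-stimulated genes 8 and 13 among 24 and genes PRDM1 represses in lymphocytes 4 and 3 among 9. Hypoxia and glycolysis genes had 7 rises and 8 falls among 19 tested members, NF-kB targets 6 and 3 among 13 and RAS/MAPK feedback genes 7 and 5 among 14. TGF-beta and BMP targets showed 8 rises and 3 falls among 13 tested members, epithelial genes 1 and 5 among 8 and mesenchymal genes 4 and 1 among 8. Fibroblast markers held 2 rises and 1 fall among 4 tested members, leukocyte markers 2 and 0 among 2 and replication-dependent histone genes 2 and 1 among 12. Adjusted over the list alone, the counts of the lists reported were the same except for Wnt targets (5 rises and 5 falls) and replication-dependent histone genes (1 rise and 1 fall). The median, the mean and the test differed in sign for Wnt targets, intestinal differentiation markers, hypoxia and glycolysis genes and NF-kB targets. The total of 7557 fell to 4645 with 1 group per arm and to 639 for differences beyond 1.5-fold.

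**Figure D4:**
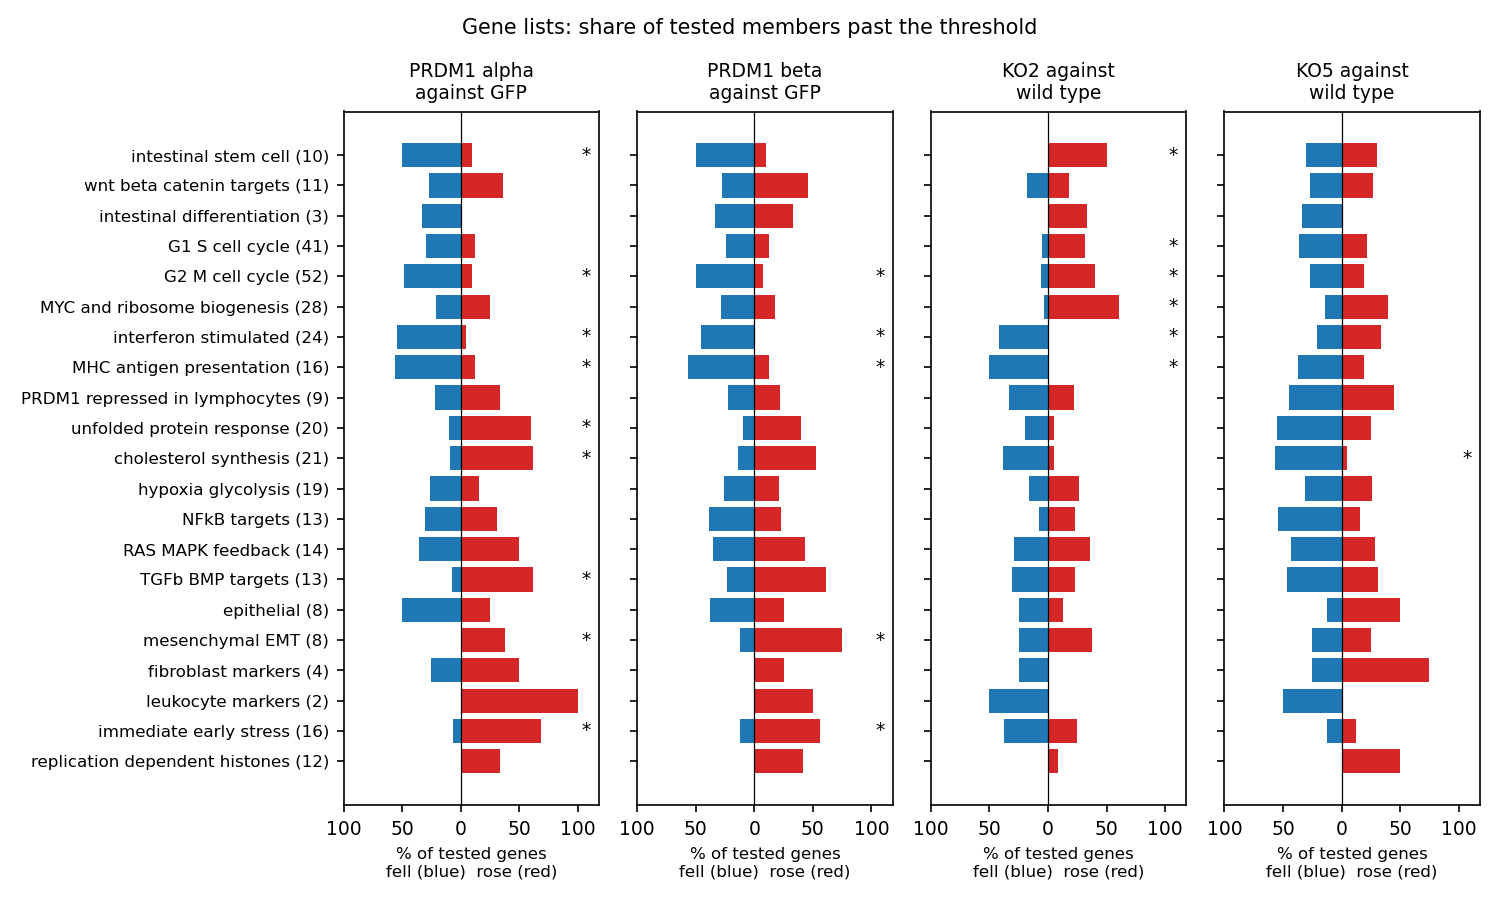
Percent of the tested members of each gene list reported that rose (red, to the right) or fell (blue, to the left) in 4 comparisons, with the number of tested members in parentheses; an asterisk marks a list with adjusted p under 0.05 at the preset correlation. Interferon-stimulated and antigen presentation genes that passed mostly fell with both forms.

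Each form was also set against the knockouts, as in the authors' deposited tables. With alpha, SERPINB7 was 8.18 ± 0.58 higher, ARL14EPL 7.86 ± 0.81, MMP3 7.80 ± 0.28 and CPA4 7.56 ± 0.13, while TLR3 was lower, at -3.19 ± 0.24, ADAMTSL1 at -3.12 ± 0.09, PDE7B at -2.59 ± 0.05 and RRP15 at -2.56 ± 0.04. With beta, ARL14EPL was 7.96 ± 0.81 higher, SERPINB7 7.30 ± 0.58, CPA4 6.42 ± 0.14 and ZFP82 6.41 ± 0.44, while TLR3 was lower, at -6.29 ± 0.70, ADAMTSL1 at -5.04 ± 0.17, GBP3 at -4.97 ± 0.45 and PDE7B at -4.25 ± 0.08. Against the knockouts, 3418 genes were higher and 2973 lower with alpha, and 3664 and 3132 with beta. Cholesterol synthesis and unfolded protein response genes passed as higher and G2/M, MYC and ribosome biogenesis and antigen presentation genes as lower with either form, at adjusted p from 7.10e-05 to 0.00689; with an estimated correlation the adjusted p was from 0.0795 to 0.259. With alpha the immediate early genes also passed as higher (adjusted p = 0.0136, and 0.144 with an estimated correlation) and the stem cell genes as lower (adjusted p = 0.0275, and 0.144 with an estimated correlation).

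At adjusted p under 0.05 the authors' deposited table for alpha held 1124 genes higher and 925 lower, and their deposited table for beta held 1316 and 1107. All 2049 genes of the authors' deposited alpha table and 2420 of the 2423 of their deposited beta table were also called here. For CDK6, the authors' deposited alpha table gave -0.49 ± 0.05 (adjusted p = 2.70e-17), where the fit here gave -0.49. For MMP3, the authors' deposited alpha table gave 1.11 ± 0.17 (adjusted p = 8.64e-10) against 7.80 here, and whether their fold changes were shrunken is not stated. The mean counts in the authors' deposited tables were rebuilt by exactly 1 of 63 sets of groups, both knockouts with the named form. The deposited table named for both forms together was identical to the beta table, so no value of it is used. With 1 group for the knockouts, 3171 genes passed with alpha and 3696 with beta here, and 576 and 594 passed beyond 1.5-fold.

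The controls of the arms were compared with each other to see what GFP overexpression and handling add. The differences were small. The apoptosis inhibitor gene BIRC3 was 0.51 ± 0.10 higher with GFP, the ciliary gene IFT88 0.44 ± 0.11, RGS2, a regulator of G protein signalling, 0.42 ± 0.12 and MYBL1 0.36 ± 0.05 (adjusted p = 4.34e-06). PABPN1, a poly(A)-binding protein gene, was lower, at -0.67 ± 0.12, RTN4R at -0.63 ± 0.08, C20orf24 at -0.54 ± 0.13 and the small nucleolar host gene SNHG19 at -0.54 ± 0.08. PRDM1 did not differ detectably, at a ratio of 1.75 (95% interval 0.572 to 5.34). In all, 1133 genes were higher and 1311 lower, with 6 and 12 at least 2-fold. Of 41 G1/S genes 9 were higher and 2 lower (adjusted p = 0.0138, and 0.949 with an estimated correlation), and adjusted over the list alone 11 and 2. That list call ended after removal of the GC trend described next, at adjusted p = 0.357, and unfolded protein response genes (1 higher and 0 lower, adjusted p = 7.02e-04) newly passed, though not with an estimated correlation (0.147). The fold changes fell with transcript GC content across 11020 genes (Spearman -0.74), and after removal of that trend 188 genes passed, IFT88 and RGS2 not among them. The total of 2444 was 645 without wild-type replicate 2, 1079 without GFP replicate 2 and 1460 with the DESeq2 Wald test. The calls of BIRC3, IFT88 and RGS2 ended without wild-type replicate 2, at 0.38, 0.25 and 0.46, and those of IFT88 and RGS2 also without GFP replicate 2, at 0.36 and 0.40. Beyond 1.5-fold, edgeR passed 0 genes, with 33 at an unadjusted p under 0.05.

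The last comparison asked whether overexpression and knockout move the same genes in opposite directions. RRP15 rose by 0.72 ± 0.03 in the knockouts, fell by 1.84 ± 0.04 with alpha and fell by 2.30 ± 0.05 with beta. IGF2BP3, higher in both knockouts, fell by 0.95 ± 0.04 with alpha and fell by 1.10 ± 0.04 with beta. ZFP82, lower in both knockouts, rose by 1.06 ± 0.12 with alpha and by 0.65 ± 0.13 with beta. These 3 genes were picked for this comparison after their values were seen. Across genes, 852 rose with alpha and fell in the knockouts, where independent lists would share 519 (2-sided Fisher's exact test, p = 2.05e-68, adjusted over 16 overlaps 6.55e-68). The reverse held for 634 genes, against 362 (Fisher's exact p = 8.56e-59, adjusted 2.28e-58). The same direction was shared by 410 rises, against 472, and 285 falls, against 399. For beta the opposite overlaps were 873 and 599, against 560.2 and 400.4, and the same direction was shared by 484 rises, against 509 (adjusted p = 0.176, not passed), and 382 falls, against 441 (adjusted p = 6.87e-04). These tests treat genes as independent, which they are not. They also rest on knockout calls judged by the spread within each derivative. With the knockout libraries as 1 group only 337 genes passed, and the overlaps were not recounted for those. The correlation of fold changes was weak, with r = -0.15 (Spearman -0.16) for alpha and -0.08 (Spearman -0.12) for beta, and no library is shared. The DESeq2 Wald test was run without the low-count filter. It gave 931 genes that moved oppositely with alpha and in the knockouts and 382 in the same direction, against 1486 and 695 here. Its r of -0.03 also covers genes below that filter, so it is not like for like with -0.15. After removal of the GC trend, which has opposite signs in the 2 comparisons (Spearman 0.20 and -0.49), 1034 moved oppositely and 699 in the same direction, a smaller excess of opposite genes. Over the tested genes r was then -0.13. The same-direction genes did not become fewer (695 before), although the knockout calls fell from 4669 to 3692. The overlap of independent lists was not recomputed there, so the shortfall of same-direction genes is not shown to remain after that removal.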

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

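The tests of PRDM1 transcript dose, and that of GC content for the falls, were chosen after the result was seen, and the GC correction was added after the data were seen. Each result here is a difference between groups under the same contrast, tested directly with edgeR on 2 libraries per group. No group had the 4 libraries that a test for a single deviating library needs.

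The forms differed in 802 genes. Log2 differences of alpha over beta among the genes named, with adjusted p from 3.83e-35 to 0.0477, were as follows. Higher with alpha, in order of size, were TLR3 (3.11), GBP3 (2.93), MMP3 (2.92), MMP1 (2.05), RAB27B (2.05), JAG1 (1.97), ADAMTSL1 (1.92), PADI1 (1.76) and SNAI2 (1.66). Smaller excesses with alpha were those of PDE7B (1.66), ERAP2 (1.23), SFTA1P (1.19), PSMB9 (1.16), CPA4 (1.14), SERPINB7 (0.89), ACSL5 (0.64), TAPBP (0.56) and USP18 (0.50). Next came RRP15 (0.46), ZFP82 (0.42), CRELD2 (0.35), HMGCS1 (0.27), SKIL (0.20), IDI1 (0.16), IGF2BP3 (0.14), NCAPD2 (0.14) and CDK6 (0.14). The smallest were those of EGR1 (0.14) and HMGB2 (0.0941). Higher with beta were SCG2 (-1.56), GPRC5A (-1.41), PRDM1 (-1.28), ID2 (-0.94), CDKN2B (-0.82), JUN (-0.25), IER3 (-0.19), MYC (-0.12) and CKS2 (-0.11).

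KO5 and KO2 differed in 7062 genes, of which 5161 stayed called in the same direction after the GC correction. Log2 differences of KO5 over KO2 among the genes named had adjusted p from 7.93e-50 to 1.80e-04. Higher in KO5 were TFPI (10.56), RAB34 (8.01), COL16A1 (7.70), MFNG (6.66), ANKRD20A12P (2.59), IRF7 (1.06), NAV3 (0.82), RRP15 (0.27) and IGF2BP3 (0.24). Smaller excesses in KO5 were those of UTP20 (0.15) and WDR43 (0.14). Higher in KO2 were CSPG4 (-7.21), FAM198B (-7.09), GFPT2 (-6.54), TNS4 (-4.75), LAMB3 (-3.20), TCEB3 (-1.95), PCLO (-1.25), HMGA2 (-1.07) and INSIG1 (-0.91). Smaller excesses in KO2 were those of CCND1 (-0.54), DHCR7 (-0.47), TOP2A (-0.43), HERPUD1 (-0.23) and CDC20 (-0.15). The values of TFPI, COL16A1 and CSPG4 are fitted ones that depend on the prior count, since a group held 0, 2 or 3 counts.

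Among genes changed at least 2-fold with either form, rises that differed were mostly larger with alpha and falls that differed mostly larger with beta. The smaller rises leaned to beta (67 larger with alpha and 99 with beta), so over all shared rises that differed the forms were nearly even (135 and 125). Beta libraries held more PRDM1 transcripts, and a higher dose would make rises larger with beta. Of the 94 rises of at least 2-fold that differed 27.7% were, which argues against transcript dose alone for these rises; that share is the observed pattern itself and no separate evidence. Dose stays open for the smaller rises and for the falls, of which 96.6% of 59 were larger with beta. GC content is argued against for both parts, since after its correction 72.4% of 98 rises were larger with alpha and 96.7% of 61 falls larger with beta. A difference in what the forms do at their targets is a candidate explanation that stays open, as does the amount of protein, which was not measured. Each form is held by a single derivative, so a difference between the derivatives other than the form was not tested.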

How the results depend on the processing

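The GC correction, and the DESeq2 Wald test for overlaps, were chosen after the data were seen. Of 4541 values of the 330 named results (148 genes) under alternatives, 4267 kept their direction and side of the threshold, 271 lost the call, 1 gained it and 2 reversed. Most of these genes were named for the size or p-value of their change, so that pooled share is no independent check. With 1 group per arm 42 values lost the call and 108 stayed as they were. The reversed ones were values that did not pass: MYC with beta was -0.0176 without GFP replicate 1 (-0.0176 to 0.0614 over libraries left out), and PRDM1 in GFP against wild type -0.13 without GFP replicate 2 (-0.13 to 1.30). The number of genes called stayed within 1.5 times under DESeq2 size factors, no filter, only the compared groups, the replicate block and PRDM1 left out in all 11 comparisons. The numbers beyond 1.5-fold, smaller by construction, were 360 with alpha, 353 with beta, 59 between the forms, 126 in the knockouts, 176 in KO2, 280 in KO5 and 441 between KO5 and KO2. They were 639 for overexpression against knockout, 576 for alpha and 594 for beta against knockout, and 0 in edgeR for GFP against wild type (33 at an unadjusted p under 0.05, and 1460 for any fold with DESeq2). The DESeq2 Wald test gave 424 between the forms, 2360 in KO2 and 1460 for GFP against wild type, and overlaps of 931 opposite and 382 same-direction genes; the cause was not tested. With 1 group per arm, where the spread also holds the difference between derivatives, 337 genes passed in the knockouts, 4645 for overexpression against knockout, 3171 for alpha and 3696 for beta against knockout. Those fits still count the libraries of a derivative as separate and pool the spread with that of the other groups, so these numbers may still be too high. The authors' deposited tables held 2049 genes for alpha and 2423 for beta; the cause of the difference was not tested. That source was not run for overexpression against knockout, because the deposited table is identical to the beta one. Without single libraries, where fewer libraries carry the test, counts ranged from 395 to 495 between the forms, 2610 (without wild-type replicate 2) to 4382 in the knockouts, 2563 (without wild-type replicate 2) to 3150 in KO2 and 645 (without wild-type replicate 2) to 2110 for GFP against wild type, with 1079 there without GFP replicate 2. A lone library is assumed to vary like the other groups. After the GC correction 188 genes passed for GFP against wild type, 3692 in the knockouts, 4170 in KO2, 5300 in KO5 and 6431 between KO5 and KO2. Of 53 list calls among 242 tests, 5 held with an estimated correlation; those of lists reported were MYC and ribosome biogenesis genes in the knockouts (0.0296) and in KO2 (0.0153), and interferon-stimulated genes in KO2 (0.0350). With the GC correction 66 were called, 49 of the 53 among them and 17 new, and with the replicate block 55. With both the GC correction and an estimated correlation 10 held. Those of lists reported were MYC and ribosome biogenesis genes in the knockouts (0.0151) and in KO2 (0.0258), interferon-stimulated (0.0258) and G2/M genes (0.0258) in KO2, G2/M genes between KO5 and KO2 (0.0238), and G2/M (0.0486) and unfolded protein response genes (0.0486) for alpha against knockout. List calls were also lost where the estimated correlation lay below the preset 0.01, as for interferon-stimulated genes with alpha (-0.0181). A list call lost with an estimated correlation is therefore no sign by itself of correlated members. The share of calls that were higher in GFP against wild type was 46.4%, 55.2% with DESeq2 size factors and 58.2% with the DESeq2 Wald test. With DESeq2 size factors, PRDM1 left out or the GC correction, the median log2 fold change of all genes lay within 0.0116 of 0 in each of the 11 comparisons. Residuals of libraries with the same replicate number correlated between -0.07 and 0.06 over 15 pairs of groups.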

Other observations

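The symbol families, the zinc finger family, the tests of shared reads in each derivative, of dependence on PRDM1 and of shared history, the test of the GC trend between GFP and wild type, and the splits that keep derivatives whole were chosen after the results were seen. A family was formed by the letters before the first digit of a symbol, so it can hold genes of another function. Genes with RPL symbols, the prefix of ribosomal proteins, were slightly lower with both forms. Of 53 RPL genes 29 fell with alpha, where 8.64 would by chance (median -0.10; 1-sided Fisher's exact test, adjusted p = 7.28e-08 over 450 tests), and 27 fell with beta, where 9.55 would (median -0.08, adjusted p = 1.15e-05). Of 45 RPS genes 17 fell with alpha (median -0.06, adjusted p = 0.0378), and the test did not pass with beta (17, median -0.05, adjusted p = 0.0770). Genes with SLC symbols, the prefix of transporters, leaned up with beta. Of 213 such genes 71 rose against 48.8 by chance (1-sided Fisher's exact test, adjusted p = 0.0378), and 59 after the GC correction. Genes with EIF symbols, the prefix of translation factors, leaned up in the knockouts. Of 50 such genes 19 rose against 8.64 by chance (1-sided Fisher's exact test, adjusted p = 0.0378), and 13 after the GC correction. Medians kept their sign with DESeq2 size factors, and genes of a family are not independent.

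Zinc finger genes made up 21 of the 72 genes at least 2-fold lower in both knockouts. Of the 72, 68 could be placed in the genome, and 31 lie on chromosome 19, which holds 900 of the tested genes. All 21 zinc finger genes lie there. Their median was -2.49 in KO2, -2.18 in KO5, 1.08 with alpha and 0.36 with beta. Their summed level was 754 and 747 CPM in wild type, 182 and 185 in KO2, 232.1 in both KO5 libraries, 802 and 807 with GFP, 1753 and 1720 with alpha and 1070 and 1098 with beta. GC content is argued against, since 21 of 21 stayed called and at least 2-fold lower after its correction. Reads shared between paralogs are argued against as the whole cause, since the summed level of all tested zinc finger genes in the knockouts was 0.941 of that in wild type and lower in every knockout library. The derivatives differed here. In KO2 the other zinc finger genes were also lower, their change being -117% of the loss of the 21, which argues against shared reads there. In KO5 the others gained 47.6% of what the 21 lost. The others were also higher with GFP (12344 and 12328 CPM, against 11906 and 11911 in wild type), where the 21 did not fall. The gain by itself is therefore no sign of shared reads, which stay open for part of the fall in KO5.

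Dependence on PRDM1 is a candidate explanation, since 14 of the 21 rose with both forms, 19 with alpha and 14 with beta, while 1 fell with beta. Of the other 51 genes lower in both knockouts, 25 rose with alpha and 21 with beta. Over all 12858 tested genes, 2729 rose with alpha and 2945 with beta. The wild-type libraries held only 4 and 4 PRDM1 counts, so there was little PRDM1 transcript to lose. A history shared by both derivatives, in which neighbouring genes were silenced together, stays open. Of the 21 genes 15 neighbour pairs lay within 2 places of each other among tested genes, where 10000 random draws of as many tested zinc finger genes gave a median of 1 and at most 6. Both explanations allow such neighbours, and no unedited derivative with the same handling was sequenced. The dependence is a hypothesis found and tested on the same data.

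Many small differences between GFP and wild-type libraries may follow from GC content. Fold changes correlated with it at -0.74 (Spearman, across genes, which are not independent replicates, 1 of 11 such trends), and 188 genes passed after the correction against 2444 before, with 142 called in both. The trend was also present in the knockouts together (-0.49), in KO5 (-0.55) and in KO5 against KO2 (-0.44), and weak in KO2 (-0.08). The labels give no library batch, so what produced the trend was not tested.

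For overexpression against knockout the real split of the 8 libraries called 3903 genes in a fit with 1 group per side, the highest of the other splits 1, and 1 of the 35 splits, the real one, gave as many. The libraries are pairs from 4 derivatives, so these splits are not alike. Only 3 splits keep the derivatives whole, too few for a share under 0.05; of these the highest of the others gave 1.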
